A study of Mus musculus with 44 samples.

How the data were processed

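The deposited data are 44 Affymetrix MG-U74Av2 arrays of mouse ES cells (CGR8, clone cgr8.8 per the labels), hybridised with biotin-labelled total RNA on 1 channel each. The deposited table gives 1 intensity per probe set and array; the authors' processing notes name RMA, which corrects the background, normalises the arrays by quantiles and summarises the probes of a set, without a version or settings. The deposited intensity values are on the linear scale, with all values above 0 and medians from 106 to 112, so they were converted to log2 before any test. Which arrays were normalised together is not stated. Intensities are relative and carry no count of molecules, so depth does not apply and the number of arrays limits the precision. The files name no genome build, and no coordinates are given.

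Of 12488 probe sets, 66 Affymetrix control sets were left out and 12422 were tested without a filter on intensity. Gene symbols came from the platform annotation: 10833 probe sets had 1 symbol, 396 had several and 1193 had none. The Entrez gene IDs of 10817 of the first kind matched the RefSeq gene table of the GRCm38.p6 assembly, used for names only, and 0 symbols changed, which left 8251 distinct symbols.

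Groups came from the labels. In 4 arrays the words of the title and the array code in the same title named different clones or treatments; they were left out of every comparison, and 40 arrays remained in 11 groups. The groups were fitted together in limma 3.58.1 (R 4.3.3) with lmFit and eBayes (29 residual degrees of freedom), a moderated two-sided test, and Benjamini-Hochberg adjustment over the probe sets of each comparison at a threshold of 0.05. Errors of log2 changes are standard errors from that fit, and errors of group means are SDs. The 8 comparisons were recombined against unrecombined Hex; 4-OHT against none in recombined and in unrecombined HexERTVP2 cells, each averaged over clones; the interaction of 4-OHT with recombination; recombination of HexERTVP2 without 4-OHT; unrecombined Hex against wild type; clone 2 against clone 1; and the difference between the clones in the 4-OHT response of recombined cells. Genes called in opposite directions in the Hex comparison and in the interaction were also counted.

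The 16 gene lists were pluripotency, primitive and visceral endoderm, anterior endoderm, primitive streak and mesoderm, neuroectoderm, trophoblast, fibroblast, blood and endothelium, Nodal and TGF-β signalling, Wnt signalling, Groucho/TLE, cholesterol synthesis, oestrogen response, hypoxia and glycolysis, p53 and stress, and cell cycle. Each gene was represented by its probe set with the highest mean, and each list was tested with camera at a preset correlation of 0.01, adjusted over the 16 lists of a comparison (128 tests in all). Camera with an estimated correlation and fry were run beside it. The genes named in the text were chosen by a rule. Hhex, Tle4 and Nodal were named in each comparison. For the Hex comparison, 4-OHT in recombined cells and the interaction, the rule took up to 10 genes with the largest rise and 10 with the largest fall among probe sets with 1 symbol that passed the threshold and whose arrays did not overlap between the groups (in each clone, where clones were averaged); for the other comparisons it took up to 5 each. From a list it took up to 4 passing members, or up to 2 as values. Among the named genes Abca1, Foxp1, Egr1, Ak4, Eif2s2 and Ssbp4 also had other probe sets of the same sign that did not pass. The text prints a selection where lists are long, and says where a gene was named outside the rule.

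Groups, comparisons, lists, the naming rule and the alternatives of normalisation, filter, variance moderation, array weights, arrays fitted, replicate block, threshold and left-out arrays were fixed before the data were examined. Chosen after seeing the data were the fits without array 2 of the unrecombined Hex group in comparisons that do not use its group and in the list tests (leaving it out of the other counts was among the planned left-out arrays), the β-actin 3′/5′ log2 ratio as a covariate, the combination of these, wild type as the control for recombined Hex, and the plain 4-OHT response in place of the interaction. The procedure was tested on simulated data: changes added to 100 probe sets at each size were found at 91% for a log2 change of 1 and at 54% for one of 0.5 in the Hex comparison, and at 95% and 75% for 4-OHT in recombined cells. For the difference between clones in the 4-OHT response the shares were 73% and 14%. False calls made up 7.05% of the calls for Hex, 4.49% for 4-OHT in recombined cells and 9.20% for 4-OHT in unrecombined cells. The simulated noise was independent between probe sets and arrays, while the real residuals shared a large component that followed the β-actin ratio. The shares therefore need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.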

Results

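Gene expression was measured with 44 single-channel Affymetrix MG-U74Av2 arrays, hybridised with biotin-labelled total RNA of mouse embryonic stem (ES) cells of the CGR8 line. Hex (gene symbol Hhex) is a homeodomain transcription factor. The cells carried Hex, or the fusion HexERTVP2, targeted to Rosa26, a locus that is active in most mouse cells and is commonly used for inserted genes. As the name reads, HexERTVP2 joins Hex to an oestrogen receptor domain that responds to 4-hydroxytamoxifen (4-OHT) and to a VP activation domain. The labels divide the cells into unrecombined and recombined ones; in designs of this kind recombination is the step that lets the inserted gene be expressed, which the labels do not state. The labels placed 40 arrays in 11 groups; in 1 of them, of recombined clone 2 with 4-OHT, the array code holds a stray minus sign before 4-OHT, and the words of the title and of the source were followed. There were 4 wild-type arrays, 4 of cells with unrecombined Hex and 4 with recombined Hex. HexERTVP2 clone 1 had 5 unrecombined arrays without 4-OHT, 3 unrecombined with 4-OHT, 4 recombined without 4-OHT and 4 recombined with 4-OHT. Clone 2 had 3 arrays in each of these 4 states. The other 4 arrays had labels that contradicted themselves and took part in no comparison. The number of arrays per group, 3 to 5, limits the precision of every value below, and all p-values measure only the spread between these arrays, since the labels do not say whether arrays of a group came from separate cultures.

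The arrays had median intensities between 106 and 112. Array 2 of the unrecombined Hex group stood apart. Its mean Pearson correlation with the other assigned arrays was 0.869, its log2 intensities had an SD of 1.60 (1.79 to 1.98 on the other assigned arrays), and its β-actin 3′/5′ log2 ratio, a measure of RNA and labelling quality, was 2.24 (0.56 to 2.34 over the assigned arrays). The model uses 1 spread per probe set for all groups, so this array entered every comparison. Values without it stand beside the probe set counts of each comparison, but not beside every list count. Within groups, the first principal component of the other 39 arrays held 49.9% of the residual variance and followed the β-actin ratio (Pearson r = 0.905, Spearman ρ = 0.891, each with a two-sided permutation p of 1e-05, the smallest that 100000 permutations can give; r = 0.906 without the 2 arrays farthest from the median; 1 relation was tested). The β-actin difference is therefore given for each comparison.

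**Figure D1:**
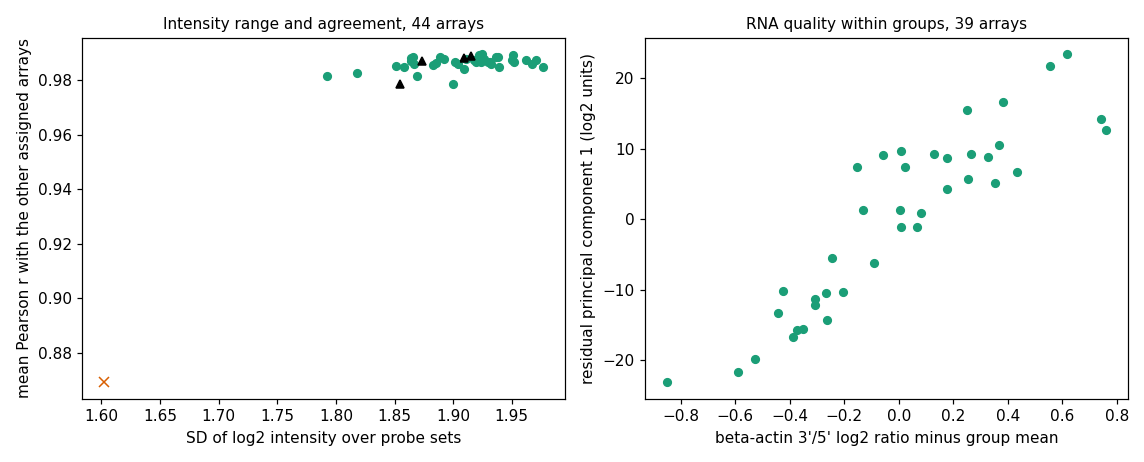
Left, SD of the log2 intensities over probe sets (x axis) against the mean Pearson r with the other assigned arrays (y axis) for the 44 arrays: circles, assigned arrays; triangles, the 4 arrays in no group; cross, array 2 of the unrecombined Hex group, at an SD of 1.60 and a mean r of 0.869. Right, β-actin 3′/5′ log2 ratio minus its group mean (x axis) against the first principal component of the residuals (y axis, log2 units) for the 39 arrays without it, with r = 0.905.

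The first comparison, recombined against unrecombined Hex cells (4 arrays each), asked which genes differ between these states of the Hex line. The genes with the largest rise that did not overlap between the groups were Dynll2 (a dynein light chain), which rose by 2.66 on the log2 scale (SE 0.44, 6.32-fold), and Calcoco2 (an autophagy receptor), which rose from 5.82 ± 0.39 to 7.94 ± 0.10 (mean ± SD, n = 4 and 4; log2 change 2.12, adjusted p = 3.44e-12). Dppa3, a gene of germ cells and naive pluripotency, rose by 1.78 (SE 0.18). Array 2 of the unrecombined group read low and enlarged these rises. The unrecombined mean was 6.01 without it and 5.82 with it in Calcoco2, and 6.64 and 6.32 in Dppa3, where recombined cells were at 8.10. Wild type lay near the recombined level in Calcoco2 (7.86 ± 0.18) and Dppa3 (8.49 ± 0.17; SD, n = 4), so these rises reflect low values in unrecombined Hex cells. Dnajc7 and Hspa1b, which encode chaperone proteins, rose by 1.60 and 1.58. Acta2 (smooth muscle actin) rose by 1.56, S100a6 by 1.42, Krt19 (a keratin) by 1.38, Phlda1 by 1.34 and Gbp2, an interferon-induced GTPase, by 1.34 (SE 0.09). Array 2 also read low in Dnajc7 (7.39, with at least 9.44 on the other unrecombined arrays), S100a6 (6.05 and 7.57) and Phlda1 (4.72 and 5.81). In Gbp2 it mattered little, with an unrecombined mean of 6.50 with it and 6.56 without it. The largest falls by the same rule were those of Abca1, a cholesterol exporter (−1.06, SE 0.17), Icam1, a cell adhesion molecule (−0.98, SE 0.26), and the transcript of the Rosa26 locus itself, Gt(ROSA)26Sor (−0.94, SE 0.13). That transcript was at 4.13 in recombined and 5.07 in unrecombined Hex cells, below the median of the arrays and not shown to exceed background. Wild type was at 5.36 ± 0.17 (SD, n = 4). In HexERTVP2 clones 1 and 2 without 4-OHT it was at 4.51 and 4.30 in recombined and 4.42 and 4.28 in unrecombined cells, with no such fall. The unrecombined clones already lay near the level of recombined Hex cells, so a fall had little room to show there, and its absence does not set Hex apart. Fip1l1 (−0.80), Rpl39l (−0.78), Pros1 (−0.78), Gm15987 (−0.71), Neurod1 (−0.71), Foxp1 (−0.69) and Bnip3 (−0.68) fell less. The calls of Icam1 and Gm15987 were lost when certain single arrays were left out.

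Nodal, a TGF-β family ligand, was at 7.33 ± 0.30 in recombined Hex cells and 7.95 ± 0.54 in unrecombined ones (SD, n = 4 each), with wild type at 7.88 ± 0.13. Its log2 difference between the Hex groups was −0.62 (SE 0.18) at an adjusted p of 0.0502, just outside the threshold. Without array 2, on which Nodal stood at 7.15 against at least 8.17 on the other 3 arrays, the difference was −0.89 (SE 0.15, adjusted p = 2.17e-04). Tle4, a Groucho-related co-repressor, differed by −0.21 (SE 0.28, adjusted p = 0.739), and by −0.57 (SE 0.25, adjusted p = 0.189) without array 2; with the β-actin covariate as well it passed (−0.61, adjusted p = 0.0309). Both genes were named by the study from these arrays, so their values here are no independent evidence. The Hhex probe set read 6.25 ± 0.15 in recombined Hex cells, 5.89 ± 0.64 in unrecombined ones and 6.14 ± 0.06 in wild type (SD, n = 4 each; adjusted p = 0.243 between the Hex groups). Whether the inserted gene contains the sequence that this probe set detects is not known from the files, so the value is no measure of its expression.

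**Figure D2:**
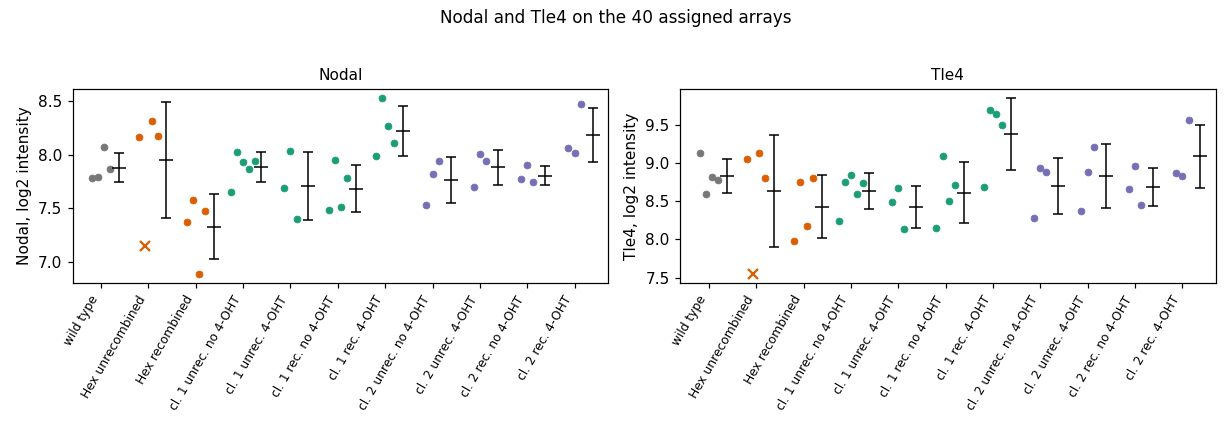
Log2 intensity (y axis) of Nodal (left) and Tle4 (right) on the 40 assigned arrays, by group (x axis; cl., HexERTVP2 clone; rec. and unrec., recombined and unrecombined). Each point is 1 array, the cross is array 2 of the unrecombined Hex group, and bars give the group mean ± SD. Mean Nodal was lowest in recombined Hex cells (7.33); it was 8.22 and 8.18 in recombined clones 1 and 2 with 4-OHT, and 7.95 in unrecombined Hex cells (8.22 without the cross).

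Among the fixed gene lists, 4 of 25 measured pluripotency genes rose in recombined Hex cells and 0 fell, with Dppa3, Nanog (0.65) and Klf2 (0.53) the largest. Array 2 enters these values. The unrecombined mean of Klf2 was 8.32 with it and 8.49 without it, against 8.85 in recombined cells. Of 35 primitive and visceral endoderm genes 4 rose and 0 fell, among them the keratins Krt19 and Krt8 (1.02) and the collagen Col4a1 (1.10). In the anterior endoderm list 1 of 14 rose (Dkk1, 0.25). Of 27 neuroectoderm genes 1 rose (Nes, 0.65) and 2 fell (Gbx2, −1.14, and Neurod1). Of 21 fibroblast genes 2 rose (Acta2 and Tagln, 1.20), and of 26 blood and endothelium genes 3 rose (Kit, 0.75, Etv2, 0.37, and Cd34, 0.25). In the trophoblast list 1 of 18 rose (Tfap2c, 0.60), in the Wnt list 2 of 39 (Fzd2, 0.86, and Dkk1), in the oestrogen response list 1 of 16 (Xbp1, 1.29), in the p53 and stress list 2 of 23 (the heat shock genes Hspa1b and Hspa1a, 0.71) and in the cell cycle list 1 of 26 (Aurkb, 0.50), and in each of these 5 lists 0 fell. In the hypoxia and glycolysis list 1 of 22 rose (Egln1, 0.30) and 1 fell (Bnip3). None passed among 29 primitive streak and mesoderm genes (Foxf1 −0.51, Foxc1 −0.35), 25 Nodal and TGF-β genes (Nodal −0.62, Lefty1 0.45), 4 Groucho/TLE genes (Tle1 0.27, Tle4 −0.21) or 17 cholesterol synthesis genes (Ebp 0.52, Msmo1 0.46). Adjusted over the list alone, the counts that rose and fell were 4 and 0 for pluripotency, 8 and 0 for primitive and visceral endoderm, 3 and 3 for neuroectoderm, 3 and 0 for anterior endoderm, for fibroblast and for oestrogen response, 2 and 1 for cholesterol synthesis and for hypoxia and glycolysis, 2 and 0 for cell cycle, and 0 and 1 (Nodal) for the Nodal list; the other lists kept their counts. The calls of Tbx3, Serpinh1, Dkk1, Nes, Etv2, Cd34, Fzd2, Xbp1, Egln1 and Aurkb each ended when certain single arrays were left out.

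Over all 12422 probe sets, 419 passed the threshold in this comparison, 322 higher and 97 lower with Hex recombined (76.8% higher), and with each array centred on its median the split was 193 higher and 144 lower (57.3%). Without array 2 of the unrecombined group 778 passed, 292 higher and 486 lower, of which 284 were among the 419; single recombined arrays also moved the count (273 without array 1, 233 without array 2), and 8 passed when only these 8 arrays were fitted. None of the 16 lists was called with all arrays (lowest adjusted p 0.277). Without array 2, camera called primitive and visceral endoderm up (7 of 35 rose; adjusted p = 0.00206, and 0.132 with an estimated correlation), fibroblast up (4 of 21; 7.09e-04, and 0.250), anterior endoderm up (1 of 14; 0.0143, and 0.248), blood and endothelium up (1 of 26; 0.0249, and 0.510) and cell cycle down (1 of 26 fell, Mki67 −0.54; 7.09e-04, and 0.429), each pair giving the adjusted p with the preset and with the estimated correlation. Without that array Cdkn1c (−1.75) and Gbx2 (−1.52) had the largest falls, and Nodal, Ski (−0.57), Inhbb (−0.37) and Skil (−0.28) fell in the Nodal list. The β-actin ratio was lower by 0.34 with Hex recombined (1.14 against 1.48), and the difference was −0.09 without array 2.

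Against wild type, recombined Hex cells differed at 33 probe sets with all arrays (13 higher, 20 lower) and at 170 (34 higher, 136 lower) without array 2 of the unrecombined group, which here enters through the spread only. Nodal differed from wild type by −0.55 (SE 0.18, adjusted p = 0.389; 0.0427 without that array) and Tle4 by −0.41 (SE 0.28, adjusted p = 0.675).

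In recombined HexERTVP2 cells, 4-OHT is meant to activate the fusion protein, which no value here measures, and the comparison asked which genes respond to 4-OHT (7 arrays with and 7 without 4-OHT, averaged over the clones). Zic2, a neural transcription factor, rose by 0.61 (SE 0.10, adjusted p = 0.00359), although its other probe set did not move with it. A probe set without a gene symbol rose by 0.52. Egr1, an immediate-early gene, fell by 0.53 on the log2 scale (SE 0.08, adjusted p = 0.00193), from 8.19 to 7.66. Inhbb, a subunit of the TGF-β family ligand activin B, fell by 0.47 (SE 0.09, adjusted p = 0.0263), a call that ended when any of several single arrays was left out. These 4 were all the calls, 2 higher and 2 lower. Inhbb was at 5.19 and 5.23 in recombined clones 1 and 2 without 4-OHT and at 4.81 and 4.67 with it. Unrecombined clones without 4-OHT were at 4.75 and 4.82. The same 7 recombined arrays without 4-OHT enter its fall, its interaction and its rise with recombination, so these are not separate results. All these values lay below the median of the arrays and are not shown to exceed background. The β-actin ratio differed by −0.15, from −0.62 in clone 1 to 0.32 in clone 2.

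Nodal was higher with 4-OHT by 0.46 (SE 0.14, adjusted p = 1) and Tle4 by 0.59 (SE 0.21, adjusted p = 1), and neither passed, nor did Hhex (−0.05, SE 0.12); without array 2 of the unrecombined Hex group the adjusted p-values of Nodal and Tle4 were 0.0916 and 0.482. With the β-actin covariate as well, Nodal passed (0.40, adjusted p = 0.00665) and Tle4 did not (0.51, adjusted p = 0.136). By clone, the differences in Nodal were 0.54 (SE 0.18) in clone 1 and 0.38 (SE 0.21) in clone 2, and those in Tle4 were 0.77 (SE 0.28) and 0.40 (SE 0.32). With the β-actin ratio as a covariate the order of the clones turned: 0.27 and 0.52 for Nodal, 0.40 and 0.60 for Tle4. In clone 1, Tle4 was at 9.38 ± 0.47 with and 8.61 ± 0.40 without 4-OHT (SD, n = 4 each).

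The Groucho/TLE list was called up in this comparison (4 measured genes, 0 past the threshold over all genes, 2 adjusted over the list alone: Tle4 and Tle3, 0.34; camera adjusted p = 6.23e-05, and adjusted p = 0.0204 with an estimated correlation). Since the study picked Tle4 on these arrays, that direction is no independent evidence. The pluripotency list was called down (25 genes, 0 past the threshold over all genes; adjusted over the list alone 1 rose, Nr0b1, 0.46, and 3 fell; adjusted p = 0.00400, but 0.779 with an estimated correlation). Inhbb in the Nodal list and Egr1 in the p53 and stress list were the only list members past the threshold on the probe sets that represent the lists; Zic2, in the neuroectoderm list, is represented there by its other probe set.

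Without array 2 of the unrecombined Hex group, which is not part of this comparison, 18 probe sets passed, 6 higher and 12 lower, the 4 above among them. The other genes that then passed were Tle3, Nr0b1, Dll1 (0.21) and a further probe set without a symbol (0.35) among those higher and, lower, Klf2 (−0.37), Gbp2b (−0.36), Tfap2c (−0.36), Prss23 (−0.33), Gbp2 (−0.32), Nr5a2 (−0.31), Calcoco2 (−0.47), Fbxo15 (−0.39), Cpt1a (−0.25) and Ceacam1 (−0.24). Klf2, Nr5a2, Nr0b1 and Fbxo15 belong to the pluripotency list. Their fold changes were the same in both fits, and only the spread differed. Nr0b1, Dll1, Calcoco2, Fbxo15 and Tfap2c lay outside the naming rule and were listed after their values were seen, since the list is short.

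In unrecombined HexERTVP2 cells (6 arrays with and 8 without 4-OHT), which served as the control for 4-OHT itself, limma called 0 probe sets; 169 had an unadjusted p under 0.05, fewer than the 5% that chance gives. Without array 2 of the unrecombined Hex group the counts were 0 and 541. In recombined cells 191 probe sets had an unadjusted p under 0.05 by the same test with all arrays, and 452 without that array. Those counts lie under the 5% that chance gives too, so this measure does not set recombined cells apart. In unrecombined cells Nodal differed by −0.03 (SE 0.14), Tle4 by −0.04 (SE 0.21) and Hhex by 0.04 (SE 0.12). None of the 16 lists was called, among them the oestrogen response list (0 of 16 genes past the threshold, adjusted p = 0.731). The β-actin ratio differed by 0.21.

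The difference between the 4-OHT responses of recombined and unrecombined cells was tested directly. Prss23, a serine protease, had an interaction of −0.63 (SE 0.10, adjusted p = 0.00628) and Egr1 one of −0.64 (SE 0.11, adjusted p = 0.0197), and these were the only calls, 0 higher and 2 lower. The Egr1 call ended when any of several single arrays was left out, which gave a count of 1. The interaction was 0.49 (SE 0.20) for Nodal 0.63 (SE 0.30) for Tle4 and −0.10 (SE 0.17) for Hhex, and none of them passed. Egr1 was the only member of the 16 lists to pass, and no list was called. Without array 2 of the unrecombined Hex group 8 probe sets passed, with Inhbb (−0.62), Calcoco2 (−0.62), Cited2 (−0.51), Tfap2c (−0.46), Klf2 (−0.42) and the probe set without a symbol (0.54) added. The β-actin ratio had an interaction of −0.36.

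**Figure D3:**
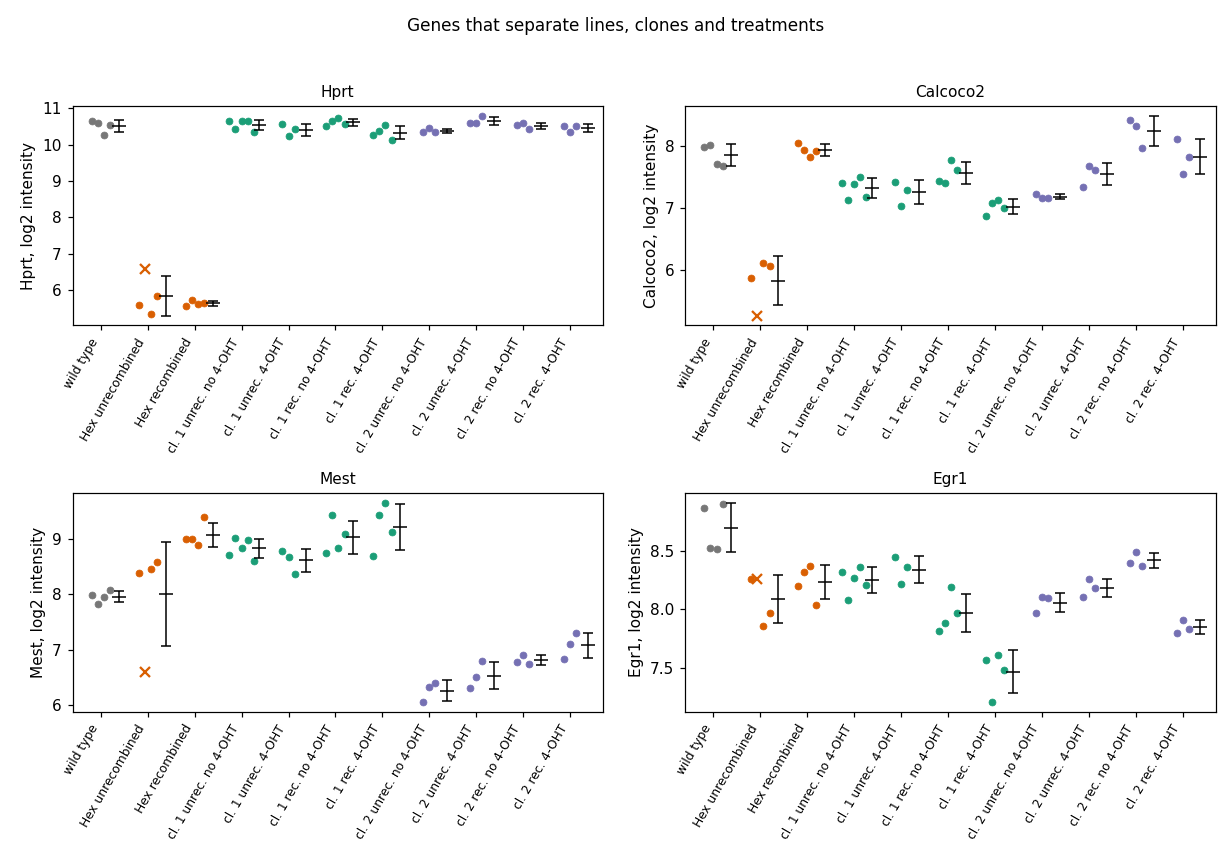
Log2 intensity (y axis) of Hprt, Calcoco2, Mest and Egr1 on the 40 assigned arrays, by group (x axis; cl., HexERTVP2 clone). Each point is 1 array, the cross is array 2 of the unrecombined Hex group, and bars give the group mean ± SD. Hprt was at 5.64 in recombined Hex cells and at 10.5 in wild type, Mest differed by −2.58 between clone 2 and clone 1, and Egr1 fell by 0.53 with 4-OHT in recombined HexERTVP2 cells.

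Probe sets called in opposite directions in the Hex comparison and in the interaction were counted. Prss23 was the 1 gene of this kind: it rose by 0.81 (SE 0.09) with Hex recombined and had the negative interaction above, against 0.0518 probe sets expected from independent lists. That interaction combines a difference of −0.33 in recombined cells, which did not pass (adjusted p = 0.0745), with one of 0.30 in unrecombined cells, where clone 2 went from 4.98 to 5.57 with 4-OHT and clone 1 stayed at 5.52. It therefore does not show that activating the fusion lowers Prss23. Prss23 read 4.41 in unrecombined and 5.22 in recombined Hex cells, below the median of the arrays and not shown to exceed background. With the dimmest 40% of probe sets left out, 0 opposite genes remained. No probe set was called in the same direction with all arrays. Without array 2 there were 4 opposite genes (Prss23, Calcoco2, Klf2 and Tfap2c, all higher with Hex) and 1 in the same direction (Inhbb), against 0.204 and 0.297 expected. With the plain 4-OHT response of recombined cells in place of the interaction, 0 were opposite and 1 was the same (Zic2, which rose by 0.45 with Hex); without array 2 the 8 opposite genes were Calcoco2, Dll1, Gbp2, Gbp2b, Klf2, Nr0b1, Prss23 and Tfap2c, and Inhbb and Zic2 moved the same way. Nodal and Tle4 were not among the genes of these fits. Wild type limits what the rises with Hex mean. In Calcoco2 and Gbp2 wild type (7.86 and 7.96) lay near recombined Hex cells (7.94 and 7.84), so their rises reflect low unrecombined values. In Klf2 and Prss23 it (8.69 and 4.85) lay between unrecombined (8.32 and 4.41) and recombined Hex cells (8.85 and 5.22). Without array 2 and with the β-actin covariate the plain response gave 11 opposite genes, Nodal among them, and 6 in the same direction, against 2.20 and 2.42 expected. Across all probe sets the changes in Hex and the interaction correlated at r = 0.0691, and at 0.218 without array 2; probe sets are not independent replicates.

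Recombination of HexERTVP2 without 4-OHT (7 recombined against 8 unrecombined arrays, averaged over clones) was examined next; an effect of the fusion or of recombination is not separated here from drift between lines kept apart. Bmp4 rose by 0.86 (SE 0.19) on a probe set with possible cross-hybridisation, while its other probe set was not called. Ak4, an adenylate kinase, rose by 0.75 (SE 0.09), Aard by 0.70, Prss23 by 0.61 (SE 0.07, adjusted p = 5.41e-06), Eif2s2 by 0.55 and Inhbb by 0.42. Rpl39l fell by 0.47 on the log2 scale, Psmb9, an immunoproteasome subunit, by 0.39, and Trh by 0.61. Inhbb and Trh are named as the passing members of the Nodal and the anterior endoderm lists. The pluripotency list was called up (25 genes, 0 past the threshold over all genes, 7 rose adjusted over the list alone, with Klf4 at 0.56 and Dppa3 at 0.55; adjusted p = 2.29e-04, but 0.630 with an estimated correlation). The same 7 recombined arrays without 4-OHT enter the 4-OHT comparison, where this list was called down, so these opposite calls are not separate results. By clone, Dppa3 was at 7.65 in unrecombined and 7.89 in recombined cells of clone 1, and at 6.99 and 7.84 in clone 2. Nodal (−0.08, SE 0.14) and Tle4 (−0.02, SE 0.21) did not pass, nor did Hhex (0.10, SE 0.12). The β-actin ratio was higher by 0.44 in recombined cells.

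In all, 58 probe sets passed, 48 higher and 10 lower, and 420 without array 2 of the unrecombined Hex group, with the 58 among them. With the β-actin covariate 93 passed, 46 of the 58 among them. Leaving out single arrays of clone 2 gave 149 (unrecombined array 1), 32 (unrecombined array 2), 25 (unrecombined array 3), 33, 34 and 36 (recombined arrays 2, 3 and 4), and leaving out unrecombined array 2 or 5 of clone 1 gave 37. Certain of these ended the calls of Bmp4, Eif2s2, Inhbb and Trh.

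Unrecombined Hex cells were compared with wild type (4 arrays each) next. The labels give CGR8 for all cells, but the files do not settle whether the Hex line and the wild type share a parental line, so the differences cannot be assigned to the targeting. Hprt, the purine salvage enzyme used as a selectable gene in ES cells, was lower by 4.68 on the log2 scale (SE 0.15; adjusted p = 4.17e-22; −4.93 without array 2). Its signal in Hex cells lay below the median of the arrays and is not shown to exceed background, so the difference is a lower bound. It was at 5.84 ± 0.54 in unrecombined and 5.64 ± 0.06 in recombined Hex cells, at 10.5 ± 0.17 in wild type (SD, n = 4 each) and above 10.1 on each HexERTVP2 array. Dynll2 (−2.28), Dppa3 (−2.17), Calcoco2 (−2.03) and Dnajc7 (−1.73) were the other large falls, the same genes that led the rise with recombination of Hex. Both comparisons use the same 4 unrecombined Hex arrays with opposite sign, so a gene's change in one is not a separate result in the other. Dnajc7 stood at 7.39 on array 2 and at 9.44 or more on the other arrays of its group. Rpl39l (0.88), Rreb1 (0.70), Vegfc (0.65), Klhl9 (0.64) and Vmn2r26 (0.62) were higher. The Vmn2r26 call rested on array 2, without which its difference was 0.22 (adjusted p = 0.112). Nodal (0.08, SE 0.18), Tle4 (−0.20, SE 0.28) and Hhex (−0.26, SE 0.16) did not pass.

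The pluripotency list was called down (5 of 25 fell, 7 adjusted over the list alone; Dppa3, Nanog −0.97, Klf4 −0.82 and Zfp42 −0.75; adjusted p = 0.0157, but 0.738 with an estimated correlation), and the primitive streak and mesoderm list was called up with 0 of 29 members past the threshold (Foxf1 0.53, Snai2 0.38; adjusted p = 0.0157, but 0.738 with an estimated correlation). Neither list was called without array 2. Of the neuroectoderm genes 4 of 27 rose, among them Gbx2 (0.87) and Neurod1 (0.57), and 1 fell. In total 599 probe sets passed, 94 higher and 505 lower, and 451 without array 2 (145 higher and 306 lower, 317 of them shared). The count was 1302 without unrecombined array 1, 1595 without array 3, 378 without wild-type array 2, 383 without wild-type array 4, and 14 when only these 8 arrays were fitted. The β-actin ratio was higher by 0.28 in unrecombined Hex cells, and by 0.03 without array 2.

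The HexERTVP2 clones were compared as unrecombined cells without 4-OHT (clone 2, 3 arrays, against clone 1, 5 arrays). Col4a1, a basement membrane collagen, was higher in clone 2 by 1.21 (SE 0.19), Erdr1 by 1.04, Lama1, a laminin, by 0.74 (SE 0.14), Ssbp4 by 0.68 and Cubn, an endocytic receptor of the visceral endoderm, by 0.68 (SE 0.10). The probe sets of Erdr1 and Cubn are of kinds with possible cross-hybridisation, and the other probe set of each gene was not called. Mest, an imprinted gene, was at 6.26 ± 0.18 in clone 2 and 8.83 ± 0.17 in clone 1 (SD, n = 3 and 5; log2 difference −2.58, adjusted p = 8.83e-08). The interferon-induced GTPases Gbp2 (−1.67), Gbp2b (−1.61) and Gbp3 (−1.40) and the homeobox gene Rhox5 (−1.40) were also lower in clone 2. The primitive and visceral endoderm list was called up (5 of 35 rose, 7 adjusted over the list alone; Col4a1, Lama1, Col4a2 0.57 and Sox17 0.50; adjusted p = 3.56e-04, and 0.0908 with an estimated correlation). Cholesterol synthesis was called down (1 of 17 fell, Sc5d −0.88, and 5 adjusted over the list alone; adjusted p = 0.0224, and 0.0888 with an estimated correlation), as was hypoxia and glycolysis (1 of 22 fell, Bnip3 −0.56, and 2 adjusted over the list alone; adjusted p = 0.0224, and 0.715 with an estimated correlation).

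In this comparison 250 probe sets passed, 79 higher and 171 lower in clone 2, and 1555 passed without array 2 of the unrecombined Hex group, with the 250 among them. The balance of directions was not stable: 194 were higher and 135 lower without clone 2 array 2, 455 and 390 with the β-actin covariate, and 728 and 827 without array 2 of the unrecombined Hex group. Leaving out clone 1 array 1, 3 or 4 gave 128, 138 or 120, and leaving out clone 2 array 3 gave 61. Certain of these ended the calls of Erdr1, Ssbp4, Sox17, Sc5d and Bnip3. Nodal (−0.12, SE 0.19), Tle4 (0.06, SE 0.29) and Hhex (−0.05, SE 0.16) did not pass. The β-actin ratio differed by −0.15.

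The response to 4-OHT in recombined cells was not shown to differ between the clones: limma called 0 probe sets for that difference, 92 had an unadjusted p under 0.05, and 274 did so without array 2 of the unrecombined Hex group. The difference was −0.16 (SE 0.28) for Nodal, −0.37 (SE 0.42) for Tle4 and 0.10 (SE 0.24) for Hhex, and no list was called with all arrays. With the β-actin covariate the differences were 0.25, 0.20 and 0.25, so the signs of those in Nodal and Tle4 depend on that correction. The β-actin ratio differed by 0.95 in the same contrast, the largest such difference of the 8 comparisons.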

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

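In this part the tests of array 2, of the shift of either Hex group, of 4-OHT acting without the recombined gene and of RNA quality were chosen after the results were seen; the tests that place array 2 by direction and divide the unrecombined arrays replaced earlier ones; the counts over other splits of the arrays were planned before they were run.

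Array 2 of the unrecombined Hex group lay far from the other 3 arrays of its group in the SD of its log2 intensities (1.60), in the β-actin ratio (2.24) and in its mean correlation with other arrays (0.869). RNA of wild-type or HexERTVP2 cells in its place is argued against by Hprt, at 6.58 on this array and at least 10.1 on those. A compressed intensity range is a candidate explanation: its log2 values had a slope of 0.72 on the mean of the other arrays of its group, against 0.93 to 1.04 for every other array. RNA of recombined Hex cells stays open. With the compression removed, the array lay −29.2% of the way from the unrecombined to the recombined mean over genes higher with Hex (recombined arrays from 78.9%). Over genes lower with Hex it lay at 145%. On average it therefore read lower than both groups in both sets. Examples are Calcoco2 (5.25, with unrecombined arrays from 5.87 and recombined from 7.83) and Dppa3 (5.36, from 6.45 and 8.06). Earlier measures that pooled both sets average the opposite positions of the sets and decide nothing. They were a share of probe sets nearer the recombined mean, written before it was seen (62.9%), and a position that replaced it (75.4%). Single genes departed from the average. Rpl39l, lower with Hex recombined, was at least 7.71 on all unrecombined arrays, array 2 included, and at most 7.37 on the recombined ones.

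Recombined and unrecombined Hex cells differed at many probe sets, and the tables speak for shifts of both groups. With the β-actin covariate 100% of the 778 probe sets called without array 2 were also called in the same direction. This does not test RNA quality as the cause, since the ratio differed by only −0.09 between the Hex groups without array 2. With that near balance the covariate raised the count to 1638, and few calls could be lost. The small difference itself leaves little for the measured ratio to account for. A shift of the unrecombined cells away from wild type is consistent with a median of 62.5 called probe sets at which recombined Hex and wild type both differed from them in the same direction, with the unrecombined arrays divided between the comparisons (1.42 expected from independent lists; 1 in the other direction). A shift of the recombined cells is consistent with a median of 20.5 called also against wild type in the same direction, with the recombined arrays divided (1.42 expected; 1.5 in the other direction). The design holds 1 line per state, so an effect of Hex and a drift of the line cannot be separated further.

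The probe sets called for 4-OHT in recombined cells without array 2 (18) may follow activation of the fusion. For these probe sets, an effect of 4-OHT of similar size without the recombined gene is argued against by their median change of −0.0336 in unrecombined clones. It is signed by the change in recombined ones, where it was 0.36. Leaving out single arrays of the unrecombined clones gave −0.06 to −0.02. The 18 were selected by their change in recombined cells, which raises the 0.36, and probe sets called by chance would give the same contrast. The interaction, which tests the difference directly, called 8 without array 2. With the β-actin covariate 100% of the 18 stayed called. This does not decide on RNA quality, since ratio differences of −0.62 in clone 1 and 0.32 in clone 2 partly cancel in the average (−0.15). The covariate raised the count to 35 probe sets, so losses were unlikely. Biological explanations other than 4-OHT, such as culture conditions of the treated plates, were not tested.

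Array 2 of the unrecombined Hex group also stood apart within its group in 7 genes: Nodal (7.15), Dnajc7 (7.39), S100a6 (6.05), Phlda1 (4.72), Foxp1 (7.74), Vegfc (6.48) and Vmn2r26 (7.86). Chance marks about 1 in 20 groups: 24 groups were tested for quality measures, with 4 marked and 1.20 expected, and 105 for named genes, with 12 marked and 5.25 expected. Prss23 (−0.63) and Egr1 (−0.64) had responses to 4-OHT that differed between recombined and unrecombined cells by the interaction test. Single arrays stood apart within recombined clone 1 with 4-OHT in the GAPDH 3′/5′ log2 ratio (0.80, array 3), Hhex (6.31, array 2), Zic2 (6.34, array 4) and Prss23 (6.06, array 3), and within recombined clone 1 without 4-OHT in Ak4 (8.60, array 1) and Eif2s2 (9.56, array 4). Of the 4 arrays outside every group, that with the code for recombined clone 2 with 4-OHT and text for clone 1 had Tle4 at 9.16 and Nodal at 8.25, above the highest wild-type values of 9.14 and 8.07.

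Other splits of the same arrays into groups of the same sizes were counted, the real one included. A real count is called rare where fewer than 1 in 20 splits called as many. The shares were not adjusted over the tests, and array quality varied within groups, so a rare count does not exclude chance. For Hex, 5 of 35 splits called as many as the real 419, so the count was not rare with all arrays. The highest other called 3052, several times the real count, and the splits point to a structure of the arrays. Without array 2, 1 of 35 splits called as many (778 real, 292 highest other), a rare count. With all arrays the real count was rare for 4-OHT in recombined cells (1 of 100 splits, 4 real, 0 highest other) and the interaction (1 of 100, 2 and 1). It was rare too for recombination of HexERTVP2 (1 of 100, 58 and 11), unrecombined Hex against wild type (1 of 35, 599 and 69) and the clones (1 of 56, 250 and 70). For 4-OHT in unrecombined cells and for the clone difference in the response the real count was 0, so 100 of 100 splits call as many by construction and decide nothing (highest other 86 and 8). Without array 2 the real count was rare by this rule for 4-OHT in recombined cells (4 of 100, 18 and 1384), the interaction (2 of 100, 8 and 26) and recombination (2 of 100, 420 and 1225). It was also rare for unrecombined Hex against wild type (1 of 35, 451 and 107) and the clones (1 of 56, 1555 and 1489). The splits with 1384, 1225 and 26 called several times the real count and point to a structure of the arrays beyond the groups. In those comparisons the count of calls does not separate the real groups from that structure.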

How the results depend on the processing

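The fits without array 2 of the unrecombined Hex group in comparisons that do not use it and in the list tests, those with the β-actin covariate, wild type as control and the plain 4-OHT response were chosen after seeing the data. Repeated quantile normalisation, median centring, the filter, trend with robust moderation and the block left the counts, apart from those named next, within 1.5 times of those reported. Repeated quantile normalisation gave 1 for the interaction and 89 for recombination. The filter on dim probe sets gave 1 for the interaction and 0 opposite genes, so Prss23, itself of low signal, no longer counted as opposite. Array weights gave 1442 for Hex, 97 for 4-OHT in recombined cells, 24 for the interaction, 559 for recombination, 1543 for targeting against wild type, 890 for the clones and 11 opposite genes. At an adjusted p of 0.01 the counts were 180 for Hex, 1 for the interaction, 23 for recombination, 253 for targeting and 74 for the clones, as a stricter threshold must lower them. With only the compared groups fitted, which leaves fewer arrays for the spread, they were 8 for Hex, 7 for the interaction, 103 for recombination, 14 for targeting and 0 opposite genes.

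Leaving out single arrays of the groups compared gave 233 to 778 for Hex, 378 to 1595 for targeting, 25 to 149 for recombination, 61 to 329 for the clones, 1 to 2 for the interaction, 3 to 6 for 4-OHT in recombined cells, 1 to 4 opposite genes, and 0 in unrecombined cells and for the clone difference. Without array 2 the others were 18 for 4-OHT in recombined cells, 8 for the interaction, 420 for recombination and 1555 for the clones, with 14 list calls. The β-actin covariate gave 656 for Hex, 12 for 4-OHT in recombined cells, 4 for the interaction, 93 for recombination, 845 for the clones and 30 list calls. Without array 2 and with the covariate the counts were 1638, 35, 10, 428 and 3217 in the same order, 903 for targeting and 5 opposite genes. Wild type as the control for recombined Hex gave 33, and 170 without array 2. The plain 4-OHT response in place of the interaction gave 0 opposite genes, and 8 without array 2. Of the 8 list calls 1 held with an estimated correlation, which made 1 call in all, and fry made 5 calls, 2 of them shared. The causes of these changes were not tested beyond those that the settings themselves give.

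The labels do not give the replicate numbers as pairs, and they were not used as such: after removal of group means, 173 pairs with the same number in different groups correlated at a mean of 0.0848 (lowest −0.70, 88 above 0.1), against −0.0250 for other numbers (0.109 and −0.0335 without array 2), and 17 of 40 arrays correlated best with an array of their own number, so a weak shared component is not excluded. As a block they gave 488 for Hex, 3 for 4-OHT in recombined cells, 2 for the interaction, 76 for recombination, 637 for targeting, 345 for the clones, 1 opposite gene and 6 list calls. Of 3897 values of named genes and lists under the alternatives, 3314 kept their direction and side of the threshold, 422 fell below it, 120 rose above it, 41 changed sign without ever being called and 0 called values reversed. In dim probe sets the signal over background limits what can be seen.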

Other observations

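Several genes of the fixed lists differed between cell lines, some of them genes that also moved with Hex. In clone 2 against clone 1 (3 and 5 arrays), Acta2 was lower by 0.98 on the log2 scale, Kit, a receptor of blood and germ cell precursors, by 0.76, Tle1 by 0.68, Sox11 by 0.67 and Tfap2c by 0.56. Egr1, which fell with 4-OHT in recombined HexERTVP2 cells, was also lower in unrecombined Hex cells than in wild type (−0.61, SE 0.11, adjusted p = 2.79e-04; 4 arrays each), as was Gap43 (−0.65, SE 0.15).

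The 4 arrays outside every group had titles in which the text and the array code disagreed, and they are given as values only. Array A had the code of clone 1 and the text of clone 2, unrecombined with 4-OHT in both; array B had the code of unrecombined clone 2 with 4-OHT and text without 4-OHT; array C had the code of recombined clone 2 without 4-OHT and the text of clone 1 with 4-OHT; array D had the code of recombined clone 2 with 4-OHT and the text of clone 1 with 4-OHT. Mest, which ran from 8.38 to 9.66 on the assigned arrays of clone 1 and from 6.05 to 7.30 on those of clone 2, was at 8.91 on array A, 6.51 on B, 6.72 on C and 7.08 on D. Rhox5, at 8.35 to 8.94 in clone 1 and 7.25 to 8.06 in clone 2, was at 8.70 on A, 7.27 on B, 8.13 on C and 8.03 on D. Hprt was between 10.5 and 10.8 on these 4 arrays, and at least 10.1 on the assigned wild-type and HexERTVP2 arrays. Egr1 was at 8.54 on A, 8.09 on B, 8.35 on C and 7.90 on D. Nodal was at 7.62 on A, 7.79 on B, 7.80 on C and 8.25 on D, and Tle4 at 8.04, 8.98, 8.54 and 9.16 in the same order.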
